A study of Gallus gallus with 6 samples.

How the data were processed

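RNA-seq of jejunal mucosa was available for 6 libraries of breeder hens, 3 labelled heat-adapted and 3 labelled heat-sensitive. Per the labels' protocols, each library was made from RNA pooled from 4 hens, and 12 hens entered each group out of 25 housed per group. Adapter-ligated complementary DNA was amplified by PCR, and no molecular identifiers are mentioned in the labels, so values cover PCR copies as well as molecules. Per the submitters' processing notes, cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1 and DESeq2 were used and the genome build was GRCg6a. The order and settings of these steps, the strand setting and the handling of reads shared between near-identical genes are not given in the sources used here.

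The deposited table holds, per the file headers, FPKM values (fragment counts scaled for gene length and library size, rounded by the authors to 2 decimals) and read counts for every library. Of its rows, 15675 have FPKM values and 15676 have read counts. The deposited read counts were taken as estimated counts, because between 13.2% and 13.7% of the values in a library are not whole. They sum to 10829957 to 13070796 per library, and the FPKM values sum to 779730 to 898136. The gene symbols stand beside the FPKM values. In 19 rows the symbol had been turned into a date, and these rows were left out of the tests, which leaves 15656 genes, of which 203 are listed at 0 in all 6 libraries. RefSeq's gene table for assembly GRCg7b, another build, held 13838 of these symbols directly and 279 as synonyms only, and 1539 were not matched. It was used only for names and for which genes lie next to each other, and no coordinates are given.

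The read counts are not in the row order of the symbols. Spearman's rho between mean FPKM and mean read count of the same row was -0.0048, and 77 of the 3570 genes with an FPKM of at least 20 in every library stood beside a read count of 0 in every library. Profiles over libraries were therefore used to search for each gene's count row. Over the 3 heat-sensitive libraries, pairs of FPKM and count rows piled up at a single ratio between libraries, 22.8 standard deviations above the surroundings. For the 3 heat-adapted libraries no order of the columns gave more than 4.82 standard deviations. On a table simulated from the read counts, both groups gave such a peak, at 66.1 and 57.8 standard deviations. A count row was assigned to a gene where the log ratios over the heat-sensitive libraries lay within 0.004 and no other row lay within 0.02. This named 102 rows, against a mean of 2.58 at 24 shifted ratios. In these rows the SD over genes of log2 read count over FPKM was 0.0011, 0.0011 and 0.0018 in the heat-sensitive libraries, and 1.06, 0.958 and 0.829 in the heat-adapted ones. Columns with the same heat-adapted label in the FPKM part and the read-count part thus did not hold the same values up to a factor. Which part holds the libraries the labels describe is not given in the sources used here.

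The design fixed before the data were examined called for edgeR on read counts if any were present. Since count rows carry no gene names, results for named genes come instead from FPKM, the test fixed for that unit. Genes with a mean FPKM of at least 1 over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with an empirical Bayes fit using a mean-variance trend and robust estimation, without a block. Adjusted p-values are from limma with the Benjamini-Hochberg method, 2-sided, with a threshold of 0.05. Log2 differences are heat-adapted minus heat-sensitive on the log2(FPKM + 1) scale, which understates changes of genes with low values. The count rows were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 with TMM factors and its expression filter, and with DESeq2 1.42.0. They are reported as numbers of rows.

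A set of 37 gene lists, covering pathways of heat and gut function and markers of cell types, was fixed before the data were examined. The 35 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. A list's score in a library is the median of its members' log2 values after centring each gene on its mean over the 6 libraries. Scores were compared with a 2-sided exact permutation test, for which 3 against 3 libraries allow no p below 0.1. The text names up to 12 genes per direction with the largest difference among those past the threshold whose groups do not overlap, filled to 5 per direction with the smallest p. It also draws on the 4 members of smallest p of each list past camera, the heat shock genes HSPA8, HSP90AA1, HSPA2, HSPH1 and HSF1, and the 3 genes of highest mean FPKM. Any other gene named was chosen after its values were seen. A gene that this rule would name is not reported here.

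The limma fit was tested on simulated data in which 200 of the genes were changed. It recovered 54% of genes changed by a log2 difference of 1 with 5 false calls, and 93% at 2 with 4 false calls. The edgeR fit recovered 59% and 95% of count rows. Changed genes were drawn only from those with a mean log2(FPKM + 1) above 2, and count rows only from those above a minimum mean. Recovery of tested genes with lower values was not simulated. A simulated shift of the cell cycle list by -0.5 was called, with 0 of 34 other lists. Simulated genes varied independently, while the estimated correlation within the real ribosomal protein list was 0.876. The simulation therefore does not show how often camera calls unchanged lists in these data. To judge how often both heat-adapted parts go the same way by chance, unchanged groups were simulated 1000 times against the shared heat-sensitive libraries, gene by gene, with the observed SDs. Alternatives were other pseudocounts (0.1 and 0.5), filters, scalings and weights, leaving out each library in turn, the replicate number as a block, and other tests. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.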

Results

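Gene expression was measured in the jejunal mucosa, the absorbing lining of the small intestine, of 28-week-old breeder hens kept at 36 °C for 6 h. The heat-adapted group came from Leuang Hang Kao hens and the heat-sensitive group from SUT hens, with 3 libraries in each group and 4 hens pooled per library. The read counts summed to between 10829957 and 13070796 per library, and 11587 genes had a mean FPKM of at least 1. All libraries came from heated hens, so the comparison is between breeds under heat and holds no response to heat within a breed. Results for named genes rest on the FPKM values. For 102 genes whose read counts could be found, the ratio of read count to FPKM was constant in each heat-sensitive library, and varied between genes with an SD of 0.829 to 1.06 on the log2 scale in the heat-adapted columns. The heat-adapted FPKM and read-count columns therefore did not hold the same values up to a factor. The differences below are those of the FPKM columns unless read counts are named.

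**Figure D1:**
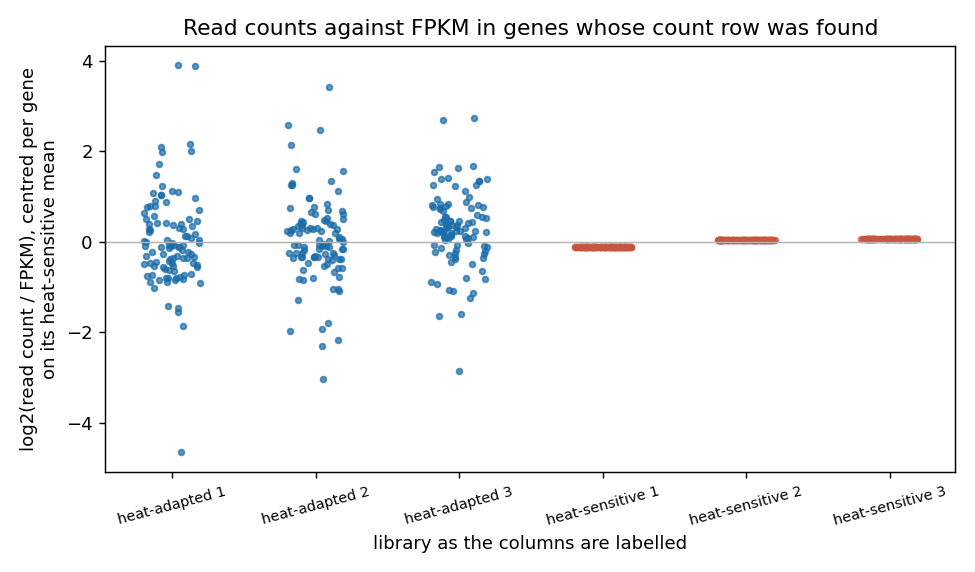
Log2 ratio of read count to FPKM, centred per gene on the mean of its heat-sensitive libraries, for the 102 genes whose count row was found through the heat-sensitive libraries; each point is a gene and each column of points a library as labelled. The points lie on a line in the 3 heat-sensitive libraries, which the search selected for, and scatter with an SD of 0.829 to 1.06 in the 3 heat-adapted ones.

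The comparison asked how the jejunum of the heat-adapted hens differed from that of the heat-sensitive hens at the same temperature. Of the genes that rose in the heat-adapted libraries, LOC107052718, an uncharacterised protein-coding gene, was the most abundant, at an FPKM of 2549 ± 482 (SD, n = 3) against 252 ± 83.8 (n = 3), a log2 difference of 3.36 (SE 0.25, adjusted p = 0.00259). HAGHL, a relative of the methylglyoxal-detoxifying enzyme glyoxalase II, was at 84.1 ± 6.68 against 25.6 ± 2.16 (log2 difference 1.68, SE 0.13, adjusted p = 0.00259). ABAT, which breaks down the transmitter GABA, was at 54.5 ± 0.565 against 21.8 ± 3.13 (1.29, SE 0.14, adjusted p = 0.0131). RAG2, which takes part in the rearrangement of antigen receptor genes, fell from 4.94 ± 1.24 in the heat-sensitive libraries to 0.0733 ± 0.0289 in the heat-adapted ones (log2 difference -2.45, SE 0.20, adjusted p = 0.00259). MZT1, a part of the gamma-tubulin complex that nucleates microtubules, fell from 42.6 ± 3.48 to 17.3 ± 2.63 (-1.26, SE 0.15, adjusted p = 0.0197).

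In all, 7 genes were higher and 4 lower in the heat-adapted libraries at an adjusted p below 0.05, and the groups did not overlap in any of the 11. The other higher genes were LOC112532770 (log2 difference 3.63), the prolactin-releasing hormone gene PRLH (1.73), the chromatin protein gene HMGA2 (1.54) and the phosphodiesterase gene GDPD4 (1.23). LOC112532770 was at 20.98, 5.18 and 13.09 in the heat-adapted libraries and at 0, 0 and 0.01 in the heat-sensitive ones. Its count row was not found, nor was that of RAG2. In the read-count part, 0 rows were at 20 or more in each library of a group and at 2 or less in each of the other. On and off differences of this kind thus rest on the FPKM columns alone. The other lower genes were LOC428505 (log2 difference -3.03), at 9.12 ± 3.77 in heat-sensitive and 0.2 ± 0.229 in heat-adapted libraries, and LOC769743 (-2.29), which lie near each other in the GRCg7b reference with LOC121109782 between them. Both are uncertain to the extent that reads of similar genes were shared, since how such reads were counted is not given. LOC112531806 did not pass (adjusted p = 0.0503); it was listed at 0 in all 3 heat-adapted libraries and at 1.84, 3.29 and 1.5 in the heat-sensitive ones.

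An unadjusted p below 0.05 was reached by 2086 genes, against 579 expected by chance, of which 826 were higher and 1260 lower in the heat-adapted libraries. After rescaling FPKM to TPM, 1357 of 2077 such genes were higher, and after median-of-ratios scaling 1083 of 2134. TPM scaling moved the median log2 difference of all genes from -0.06 to 0.05. Groups did not overlap in 2535 genes, 21.9% of those tested, where chance gives 10%. The first principal component held 46.1% of the variance and set the groups apart. Its values were 7.79 or more in heat-adapted and -7.18 or less in heat-sensitive libraries. Correlations between libraries overlapped. Heat-adapted replicate 3 had a Pearson's r of 0.977 with heat-sensitive replicate 1, against 0.980 and 0.976 with heat-adapted replicates 1 and 2. The number of called genes was 6 without heat-adapted replicate 2 and 64 without heat-adapted replicate 3.

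Among the gene lists, 19 of 35 passed camera with the preset correlation, 9 lower and 10 higher in the heat-adapted libraries. None passed with an estimated correlation (lowest adjusted p = 0.53 with an estimated correlation) or by fry (lowest adjusted p = 0.25), so the list results below are descriptions of direction across members. Scores did not overlap between groups in 8 of all 35 lists, where chance gives 10%, and single genes did not overlap in 21.9%. Of the 19 lists, 7 did not overlap. Camera had picked these on the same libraries, so 10% is not their chance value.

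**Figure D2:**
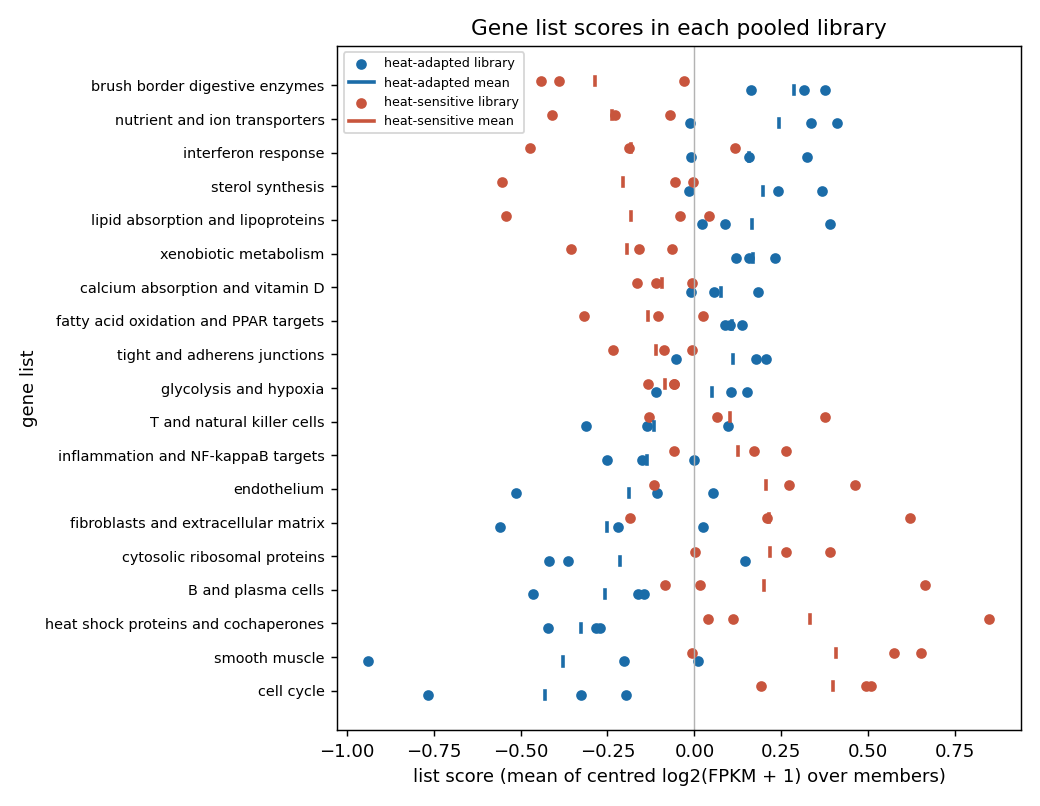
Scores of the 19 gene lists past camera, in log2 units relative to the mean of the 6 libraries. A score is the median over the list's members, although the axis label says mean. Points are pooled libraries, blue for heat-adapted and red for heat-sensitive, and short bars are group means. Cell cycle scores lay lower in all 3 heat-adapted libraries than in any heat-sensitive library and brush border scores higher, while smooth muscle and ribosomal protein scores overlapped.

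Of 41 cell cycle genes tested, 40 were lower in the heat-adapted libraries, with a median log2 difference of -0.89, and 29 passed when adjusted over the list alone, against 0 over all genes tested. The list's adjusted p was 3.72e-18 with the preset correlation, and adjusted p = 0.53 with an estimated correlation. The mitotic kinase CDK1 was at 65.3 ± 13.7 in heat-adapted and 141 ± 16.4 in heat-sensitive libraries (SD, n = 3 each), PLK1 at 6.38 ± 1.17 and 14.4 ± 1.14, AURKA at 7.31 ± 1.45 and 16.3 ± 1.83, and the nucleotide reductase subunit RRM2 at 11.8 ± 3.63 and 26.3 ± 1.09. The list's score differed by -0.83, with an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. Stem and progenitor markers had a median of -0.16 and did not pass (adjusted p = 0.39); the median was 0.04 without heat-sensitive replicate 2. Cytosolic ribosomal protein genes were lower in 67 of 68 (median -0.42), with 0 passing when adjusted over the list alone; the list passed with the preset correlation, and gave adjusted p = 0.64 with an estimated correlation. Its median was -0.16 with quantile normalization.

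Heat shock proteins and cochaperones were lower in the heat-adapted libraries for 37 of 38 tested genes, with a median log2 difference of -0.70. None passed over all genes and 13 passed when adjusted over the list alone, all lower; the list gave adjusted p = 1.05e-10 with the preset correlation and adjusted p = 0.53 with an estimated correlation. The mitochondrial cochaperonin HSPE1 was at 573 ± 111 in heat-adapted and 1090 ± 263 in heat-sensitive libraries, and the HSP90 cochaperones PTGES3, FKBP4 and AHSA1 were at 173 ± 9.22 and 288 ± 31.2, 84.6 ± 15.4 and 155 ± 45, and 93.6 ± 5.51 and 152 ± 37.7 (SD, n = 3 each). HSPA2, of the HSP70 family, was at 63.1, 54.8 and 51 in the heat-adapted libraries and at 165, 2889 and 143 in the heat-sensitive ones (adjusted p = 0.28). Heat-sensitive replicate 2 held the highest value of 33 of the 38 genes, among them HSP90AA1 at 2645, against 804 and 816 in the other heat-sensitive and 300.3 to 696 in the heat-adapted libraries. Without that library the list's median was -0.41, and HSPA2 fell in the heat-adapted group (log2 difference -1.44, adjusted p = 0.0217). HSPA8, HSPH1 and the heat shock regulator HSF1 had log2 differences of -0.64, -1.31 and -0.62 and did not pass; without that library they were -0.20, -0.59 and -0.66.

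**Figure D3:**
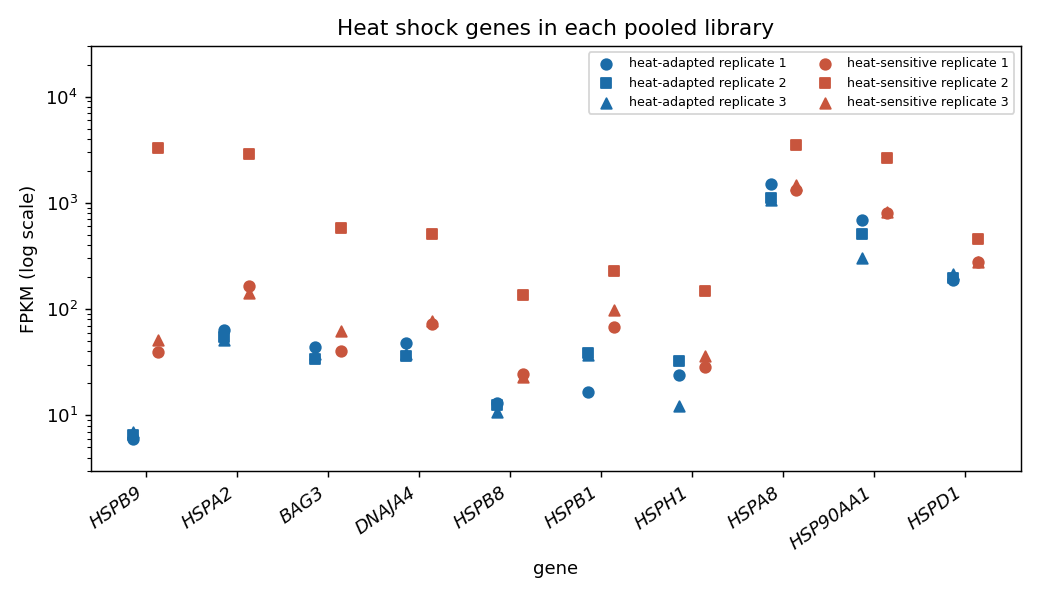
FPKM on a log scale of 10 heat shock genes in each pooled library, blue for heat-adapted and red for heat-sensitive, with symbols for replicate numbers. Heat-sensitive replicate 2 lies above all other libraries, at 3268 for HSPB9 and 2889 for HSPA2; HSPA2 in the other heat-sensitive libraries, at 165 and 143, still lies above the heat-adapted ones.

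The read counts of 7 heat shock list members could be found through the heat-sensitive libraries: HSP90AA1, HSPA2, HSPA4L, HSPA8, HSPB8, SERPINH1 and TCP1. All 7 were lower in the heat-adapted read-count columns too, with and without heat-sensitive replicate 2. HSPA2 differed by -2.93 on the log2 scale in the read counts and by -2.84 in FPKM. Its read count was 74083 in that replicate, against 3803 and 3722 in the other heat-sensitive libraries and 1111 to 2142 in the heat-adapted columns. Without that replicate the FPKM difference was -1.44. The heat-sensitive values are shared by both comparisons. With no effect at all, FPKM and read counts matched in sign for all 7 genes in 40.5% of simulations. These drew genes independently, while the heat shock list had an estimated correlation of 0.567, so 40.5% is not an exact chance value. Of 4 brush border genes found in this way, 1 was lower in the heat-adapted FPKM and 1 in the read counts, and without heat-sensitive replicate 2 these numbers were 1 and 4. Of 5 transporter genes, 0 were lower in FPKM and 1 in the read counts, and without that library 0 and 3, so the higher values of both lists below are those of FPKM. Of 4 fibroblast genes, 4 were lower in FPKM and 2 in the read counts, and without that library 3 and 0. Over the 102 genes, 71 had the same sign in both, fewer than the mean of 80 in those simulations. The covariance of the log2 differences was 0.283 against a simulated 0.17. These genes are not a sample of those tested, since a row was named only where its heat-sensitive profile stood apart from all others. Pearson's r of these differences was 0.48 against a simulated mean of 0.74. Among genes with an absolute FPKM difference above 0.5, 68% had the same sign, against a simulated 91.9%. Without the heat shock genes the covariance was 0.123, for which no value was simulated over the same genes. The smooth muscle actin ACTA2 differed by -1.22 in FPKM and 0.0003 in the read counts, and the hormone gene FGF19 by 1.20 and -1.20. With edgeR's quasi-likelihood test, 0 of 12536 count rows were higher and 3 lower in the heat-adapted columns, with 2252 at an unadjusted p below 0.05, while DESeq2 called 641.

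Brush border genes were higher in the heat-adapted libraries in 20 of 22 (median log2 difference 0.47); 9 passed when adjusted over the list alone and 0 over all genes. The list gave adjusted p = 5.15e-09 with the preset correlation and adjusted p = 0.53 with an estimated correlation. The peptidase genes MEP1B and MME were at 121 ± 6.41 against 64.5 ± 18.6 and 115 ± 46.2 against 41.1 ± 5.14 (SD, n = 3 each). Nutrient and ion transporters were higher in 25 of 32 (median 0.41), and 3 passed when adjusted over the list alone; the list gave adjusted p = 0.53 with an estimated correlation. They were the glucose transporter SLC5A1, at 843 ± 240 against 410 ± 41.9, the fructose transporter SLC2A5, at 21.2 ± 6.55 against 9.01 ± 2.6, and the neutral amino acid transporter SLC6A19, at 76.8 ± 19.4 against 37.7 ± 5.79. Xenobiotic metabolism genes were higher in 30 of 37 (median 0.33), and 4 passed when adjusted over the list alone (EPHX2, CYP2AC1, ABCG2 and ALDH3A2); this list too gave adjusted p = 0.53 with an estimated correlation, and its median was 0.19 with no filter on low values.

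Lipid genes were also higher across members. Lipid absorption genes were higher in 22 of 26 (median 0.34), sterol synthesis genes in 20 of 22 (0.37) and fatty acid oxidation genes in 20 of 25 (0.27), each passing with the preset correlation, with adjusted p = 0.53 with an estimated correlation and 0 genes passing when adjusted over the list alone. Without heat-sensitive replicate 2 the medians of the lipid absorption and fatty acid oxidation lists were 0.14 and 0.16, and that of lipid absorption was 0.21 without heat-adapted replicate 1. The sterol regulator INSIG1 was at 131 ± 30.7 against 68.5 ± 23, and AGPAT2, of triglyceride synthesis, at 112 ± 9.33 against 67.9 ± 20.3 (SD, n = 3 each). Junction genes were higher in 21 of 27 (median 0.23), although MYLK, a myosin kinase also on the smooth muscle list, was lower (log2 difference -1.25). Glycolysis and hypoxia genes were higher in 22 of 32 (0.19), led by PFKL, while LDHB and HK2 were lower. Calcium and vitamin D genes were higher in 9 of 15 (0.29), led by the carbonic anhydrase gene CA7. Without heat-adapted replicate 2 the medians of the glycolysis and calcium lists were 0.06 and 0.05, and that of the calcium list was 0.16 without heat-sensitive replicate 2 and 0.07 with no filter on low values. The calcium list's call ended without heat-adapted replicate 2 (adjusted p = 0.0692), with no filter (0.0911), with a mean FPKM of at least 5 (0.0847; median 0.15) and with TPM (0.0841), and that of the glycolysis list without heat-adapted replicate 1 (0.0872) or heat-sensitive replicate 1 (0.0584) and with quantile normalization (0.0502). These lists gave adjusted p = 0.53 with an estimated correlation; PFKL and CA7 passed when adjusted over their lists alone.

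Interferon response genes were higher in the heat-adapted libraries in 33 of 40 (median log2 difference 0.39), and the B cell, T cell and inflammation lists were lower in most members. The antiviral gene MX1 was at 26.1 ± 2.9 against 12.2 ± 3.85 and was the only interferon gene to pass when adjusted over the list alone; the list gave adjusted p = 0.53 with an estimated correlation. B and plasma cell markers were lower in 21 of 21 (median -0.50; adjusted p = 0.54 with an estimated correlation). Heat-sensitive replicate 1 held the highest score of this list, 0.66 against 0.02 and -0.09 in the other heat-sensitive libraries, and without it the median was -0.22. The markers included the immunoglobulin light chain gene IGLL1, the gene of highest mean FPKM, at 14780 ± 3487 against 25430 ± 1476, and JCHAIN, which joins secreted antibodies, at 2307 ± 161 against 3792 ± 471; JCHAIN and BCL6 passed when adjusted over the list alone. T and natural killer cell markers were lower in 31 of 40 (-0.26; adjusted p = 0.70 with an estimated correlation), with CTLA4, CD6 and CD40LG passing when adjusted over the list alone; the median was -0.11 without heat-sensitive replicate 1 and -0.17 without heat-adapted replicate 1, and the list's call ended without heat-sensitive replicate 1 (adjusted p = 0.213), heat-sensitive replicate 3 (0.0544) or heat-adapted replicate 3 (0.0595). Inflammation and NF-kappaB targets were lower in 36 of 44 (-0.33; adjusted p = 0.53 with an estimated correlation), led by VCAM1 and CCLI7, which passed when adjusted over the list alone; the median was -0.22 without heat-sensitive replicate 1 and without heat-sensitive replicate 3, and the list's call ended without the latter (adjusted p = 0.126) or heat-adapted replicate 3 (0.0896). The next genes by mean FPKM, APOA1 and FABP1 of lipid transport, had log2 differences of 0.58 and 0.40 and did not pass.

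Smooth muscle markers were lower in the heat-adapted libraries in 23 of 23 (median -0.77; adjusted p = 0.53 with an estimated correlation), fibroblast and matrix genes in 31 of 32 (-0.39; adjusted p = 0.69 with an estimated correlation) and endothelial genes in 18 of 18 (-0.35; adjusted p = 0.65 with an estimated correlation). CSRP1 was at 120 ± 36.2 against 259 ± 64.1 and was the only gene of these lists to pass when adjusted over the list alone. Scores of the 3 lists overlapped between the groups, with smooth muscle lowest in heat-adapted replicate 1. Without that library the medians of the smooth muscle and endothelial lists were -0.48 and -0.20. That of the fibroblast list was -0.23 without heat-sensitive replicate 2, -0.59 without heat-adapted replicate 2 and -0.61 without heat-sensitive replicate 3.

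Lists that did not pass camera in the main setting were endoplasmic reticulum stress (median -0.21), antioxidant defence (-0.05), goblet cells (0.07), oxidative phosphorylation (0.0015), proteasome (0.03), enteroendocrine cells (-0.15), macrophages and dendritic cells (-0.23), heterophils and defence peptides (-0.28), apoptosis and p53 targets (-0.05), glucocorticoid response (-0.09), circadian clock (0.10), enteric neurons and glia (-0.10), erythrocytes (-0.21) and liver (0.32). Immediate early genes did not pass either, and their median (-0.10) and camera direction differed in sign. The medians of the antioxidant, apoptosis, glucocorticoid and immediate early lists were above 0 after TPM scaling, and that of the enteric neuron list was -0.01 over the same genes and 0.04 when genes were filtered again on TPM. Most of the medians of these lists moved with single libraries left out, and that of the liver list was 0.05 without heat-adapted replicate 2 and 0.11 without heat-sensitive replicate 2, that of the heterophil list 0.03 without heat-sensitive replicate 1 and -0.51 without heat-sensitive replicate 2, and that of the goblet cell list -0.08 without heat-adapted replicate 1. The endoplasmic reticulum stress list passed in 6 alternatives, liver in 5 and enteroendocrine cells in 3. The exocrine pancreas list had 2 tested genes and the mitochondrially encoded list 0, too few for a test.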

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

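All tests in this part were chosen after the results were seen, except that of scaling for heat-sensitive replicate 2 and that of recounted libraries for the heat-adapted columns.

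The read counts, which the comparison of named genes does not use, matched the FPKM values in the heat-sensitive columns and not in the heat-adapted columns, for the 102 genes whose count row was found (2.58 by chance); agreement in the heat-sensitive columns was selected for in these rows and is no comparator. Count rows in another order in the heat-adapted columns are argued against, since the groups' mean log2 read counts correlated over these rows at 0.922 (across genes, which are not independent), above the highest of 1000 shuffles, 0.267. A swap among the 3 heat-adapted columns is argued against by the lowest SD over the 9 pairings, 0.78, where the same values would give a constant ratio. The same libraries counted in another way under the same labels would keep each library's deviations from its group. The highest correlation of these deviations between heat-adapted columns of the same label was 0.0429. What stays open is that the heat-adapted columns of the FPKM and of the read counts come from different sets of libraries. Both sets may be heat-adapted. Also open are the same libraries both swapped and counted in another way, which was not tested. Neither the labels nor the table tell which part holds the described libraries.

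In the read counts, 6 rows were at least 5 times as high in heat-sensitive replicate 2 as in every other library, and no other library had such a row at a count of 1000 or more. Under the same rule at an FPKM of 10 or more, heat-sensitive replicate 1 had 6 genes and heat-adapted replicate 2 had 3. Heat-adapted replicate 3 and heat-sensitive replicate 3 had 1 each, and 0 of all these were on the heat shock list. In heat-sensitive replicate 2, 6 genes met it: HSPB9 (3268), HSPA2 (2889), BAG3 (577), DNAJA4 (511), OTUD1 (138) and HSPB8 (136). Of these, 5 are on the heat shock list. Scaling of this library is argued against, since its median log2 ratio to the other heat-sensitive libraries was -0.00081 over all tested genes and 0.69 over the heat shock list, and a swap with a heat-adapted library is argued against by its correlations, higher by 0.0188 on average with the other heat-sensitive libraries. For the heat shock list as a whole, RNA of another cell type cannot be told apart. This library had the highest smooth muscle (0.65), fibroblast (0.62), endothelial (0.46) and stem cell (0.32) scores of the 6. The fibroblast list's median log2 ratio to the other heat-sensitive libraries, 0.62, was the largest among the cell type lists. It was near that of the heat shock list (95% bootstrap interval of the difference -0.12 to 0.37). The 5 heat shock genes above rose by more, HSPB9 to 3268 against 39.53 and 51.12 in the other heat-sensitive libraries. Shifts of the size of these list medians do not account for such rises. Cells outside the lists were not measured. A stronger heat response in some hens of this pool, or a difference in how they were handled, also stays open, untested.

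Cell cycle genes were lower and brush border genes higher in the heat-adapted libraries, while muscle and stroma markers were lower. As the whole cause of the brush border shift, more muscle and stroma in the heat-sensitive samples are argued against, since they would dilute goblet cell markers alike, and the medians of the lists differed by 0.40 (95% bootstrap interval over genes 0.28 to 0.71; 0.37 to 0.53 with a library left out), with the difference of scores at 0.019 or more in heat-adapted and -0.024 or less in heat-sensitive libraries. For cell cycle genes (median -0.89) they cannot be told apart, since cycling cells of those tissues were not measured apart and the smooth muscle median was -0.77 (interval -1.12 to -0.52). A larger share of crypt cells in the heat-sensitive samples cannot be told apart either. Stem and progenitor markers were lower too, in 12 of 16 tested genes, though by less than cell cycle genes. Their median was -0.16 (interval -0.40 to -0.04), 0.04 without heat-sensitive replicate 2 and -0.33 without heat-sensitive replicate 3. The interval is over genes and not pools, and cycling crypt cells were not measured apart from stem cells. A difference in cell division between the breeds, or between their responses to heat, may remain, but was not tested, since breed and heat group coincide and no unheated hens were compared.

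With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real grouping gave 11 called genes, and the highest other split 0, while 1647 genes of another split reached an unadjusted p below 0.05 with limma, against 2086 in the real grouping. It gave 3 count rows, against 1, and 3 genes with an FPKM of at least 1 in each library of a group and at most 0.1 in each of the other, against 1. Each of these results was reached by 1 of the 10 splits, the real grouping itself. For gene lists, 3 of the 10 splits gave at least 19 lists past camera with the preset correlation, and the highest other split gave 19.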

How the results depend on the processing

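The 0.1 threshold and the count-row settings other than DESeq2 were added after the data were seen. Against 11 called genes, the count was 17 and 20 with pseudocounts of 0.1 and 0.5, 7 both without a filter and with a mean FPKM of at least 5, 38 with TPM, 20 with median-of-ratios scaling, 107 with library weights and 140 at an adjusted p below 0.1. Leaving out a library gave 6 (without heat-adapted replicate 2) to 64 (without heat-adapted replicate 3). The cause of these shifts was not tested. The edgeR test on count rows called 3, on other heat-adapted values than those of FPKM. LOC107052718, HAGHL, RAG2 and LOC428505 passed in every FPKM alternative that tested them. HMGA2, GDPD4, LOC769743, MZT1, ABAT, PRLH and LOC112532770 each lost the call in at least 1, with adjusted p up to 0.137. Genes under the naming rule that did not pass in the main setting gained the call 33 times over the limma alternatives. With TPM these included LOC112531806 (adjusted p = 0.0271), PLK1 (0.0467), CDK1 (0.0467) and EPHX2 (0.0419). No called gene or list changed sign in any alternative.

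List counts were 18 to 21 in the alternatives that kept camera's preset correlation, libraries left out included, and 0 with an estimated correlation and 0 by fry. With TPM over the same genes, the medians of the T cell, junction and glycolysis lists were -0.14, 0.35 and 0.30. As deposited they were -0.26, 0.23 and 0.19. T and natural killer cells lost the call in 3 alternatives (adjusted p = 0.213 without heat-sensitive replicate 1), inflammation in 2 (0.126 without heat-sensitive replicate 3), glycolysis in 3 and calcium and vitamin D in 4. Endoplasmic reticulum stress gained it in 6 (adjusted p = 0.00828 to 0.0465), liver in 5, enteroendocrine cells in 3, macrophages and oxidative phosphorylation in 2 each (0.000433 for the latter without heat-adapted replicate 2) and the proteasome in 1. Against 3 count rows, DESeq2 called 641, and leaving out a library gave 0 to 7. Same-numbered libraries did not deviate together (correlations of -0.161, 0.11 and -0.191), which gives no sign of pairing. Deviations within groups of 3 are tied to each other, so pairing is not excluded. With the replicate block limma called 46 genes and edgeR 21 count rows. With 3 libraries per group, changes of a log2 size of 1 were recovered in 54% of simulated genes, so smaller ones can be missed.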

Other observations

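The genes in this part were chosen after their values were seen, and none passed over all genes tested. The enteroendocrine list (9 of 22 tested genes higher and 13 lower in the heat-adapted libraries) and the heterophil list (6 of 14 higher and 8 lower) did not pass camera. TAC1, the precursor of the neuropeptide substance P, was at 1.07 ± 0.164 in heat-adapted and 12.1 ± 6.18 in heat-sensitive libraries (SD, n = 3 each; adjusted p = 0.0503), and it passed when adjusted over the enteroendocrine list alone, as did SCG2 and SCG5 of secretory granules. EXFABP, a lipocalin that binds bacterial siderophores, was at 5.04 ± 1.29 against 31.7 ± 13.5, and the antimicrobial peptide gene LEAP2 was at 552 against 306; EXFABP, LEAP2, NCF4 and CSF3R passed when adjusted over the heterophil list alone. The glutathione transferase genes GSTT1 and GSTA2 and the peroxiredoxin gene PRDX4 were lower in heat-adapted libraries and the clock gene NPAS2 higher, each past the threshold when adjusted over its list alone. LOC107052719 was at 1129 ± 356 against 181 ± 88.8 (adjusted p = 0.0503), and differed by 0.70 on the log2 scale in the read counts, against 2.69 in FPKM.

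Several pools held genes of their own. Heat-adapted replicate 2 held liver and yolk genes: APOV1 was at 234 there and at most 0.18 elsewhere, ALB at 53.4 against 0.48 to 0.81, and VTG2 at 10 against at most 0.1. Heat-sensitive replicate 1 held B cell genes, with VPREB3 at 55.2 against 1.53 to 10.48 in the other libraries, CD72 at 22.7 against at most 2.91 and PAX5 at 11.6 against at most 2.11.

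In the read-count part, 0 rows were at 20 or more in each library of a group and at 2 or less in each library of the other. Pearson's r between libraries, across rows, was 0.99 to 0.992 within the heat-adapted read-count columns and 0.977 to 0.989 between these and the heat-sensitive ones. Within the heat-sensitive read-count columns it was 0.985 to 0.988, inside the range between the groups. In FPKM, Pearson's r was 0.976 to 0.984 within the heat-adapted libraries and 0.951 to 0.977 between the groups. Within the heat-sensitive libraries it was 0.976 to 0.981. The FPKM values cover the 11587 tested genes, and the read-count values all rows, those with low counts included. The height of r therefore does not compare the FPKM part with the read-count part.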
